A study of Homo sapiens with 18 samples.

How the data were processed

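Proteins and pairs of neighbouring proteins were measured as PLA products in 18 samples, with mRNA of the same barcodes in the Drop-seq and both 10x experiments. The deposited PLA files hold raw counts per PLA product and cell, and the deposited RNA files hold raw UMI counts per gene and cell. Per the submitters' processing notes, Cell Ranger 6.1.1, R 4.2.0 and Seurat 3, 3.0.2, 4.0.4 and 4.1.0 were used with the GRCh38 genome. The aligner of the Drop-seq reads and the handling of UMI in PLA reads are not given in the sources used here. The PLA panels held 13 proteins with controls in Drop-seq, 14 in the Jurkat and Raji plates, 15 in the 10x mixture and 38 in each PBMC table. No raw reads were aligned here. Gene coordinates came from the RefSeq table of GRCh38.

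RNA cells were kept with at least 500 genes and at most 15% mitochondrial counts, which left 416 of 700 Drop-seq, 6574 of 8668 10x mixture and 10367 of 12577 PBMC cells. PLA cells were kept above 10% of the median total, which left 800 of 800 Drop-seq, 157 of 192 plate, 8463 of 8668 10x mixture, 345 of 382 PBMC plate and 12562 of 12577 PBMC 10x cells. The same minimum kept 326 of 335 macrophages, spread over 4 plates. Barcodes were joined between RNA and PLA, which gave 372 Drop-seq, 6470 10x mixture and 10355 PBMC cells. Scrublet with an expected rate of 8% called 8.41% of the kept 10x mixture cells and 5.46% of the kept PBMC cells doublets, and these were left out only in an alternative.

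Clusters came from counts scaled to 10000 per cell, 2000 variable genes and 20 principal components computed with numpy. They used 15 neighbours from scikit-learn and the Leiden method of igraph 0.11.9 with seed 1. Scrublet was run through scanpy 1.11.5. The Leiden resolution was 0.3 for Jurkat and Raji RNA, 2 for PBMC RNA, 0.3 for Drop-seq and 10x PLA and 0.8 for PBMC plate PLA. Proteins with at least 0.5% of PLA counts entered PLA clusters. Clusters were named from marker lists fixed beforehand, and a PLA cluster took a name at a log2 marker ratio of 1. The score thresholds that name PBMC classes (0.5 for T cells, 0.4 for NK cells with a T-cell score of at most 0.3, and 0.5 for other classes) were set after the data were seen. So were the CD8 threshold (a mean of 2 CD8A and CD8B counts per 10000) and the CD4 threshold (a mean of 0.5). Clusters that met none were left unnamed. A PBMC cluster of 88 cells met the conventional dendritic score, at 0.634, but had no marker of that class among its leading genes. It was left out of the named classes too. In the 10x mixture, a cell was given 1 of 2 staining sets, Full or the other set, from its control probes when it had at least 2 control counts and a fold of 2. Other cells were given no set. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

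The level of a protein was the sum of its counts as probe A and as probe B. The expected count of a product was the sum over cells of its probe A total times its probe B total over the cell total. Both orders of a pair were added, except in the macrophage fits over time, where each order was a separate product. Alternatives were an expectation iterated over 20 rounds that removes excess products from the probe totals, and totals pooled over cells. Intervals at the 95% level were exact Poisson for counts and for the protein shares of macrophage samples, and exact Clopper-Pearson for shares of cells. A count of 0 was read as at most 3 counts. Products with at least 100 observed counts could be among the 8 highest named per class, beside pairs fixed beforehand.

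Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 on counts summed per sample or per platform and class, at a Benjamini-Hochberg adjusted threshold of 0.05. RNA of Jurkat-like against Raji-like cells was fitted by edgeR quasi-likelihood with TMM scaling and platform as a block (genes with at least 10 counts in at least 2 sums), with classes from PLA. Proteins of the same lines were fitted on PLA totals with platform as a block, with classes from RNA clusters or well names. Macrophages were compared between times with stimulus as a block and between stimuli with time as a block, with 4 residual degrees of freedom, for proteins and for products with at least 10 counts in at least 3 sums. The untreated sample stood alone and was compared without a test. Proximity over time was fitted by limma on log2 ratios with a pseudocount of 1, for products with at least 20 observed or expected counts. The pipeline was tested on simulated data.

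The choices of groups, tests, gene lists and named pairs were made before the data were examined. Genes were named as the 12 with the largest fitted log2 change in each direction among those past the threshold, changed the same way in both platforms and with at least 50 CPM in both sums of the higher class. Genes that code for panel proteins and the leading members of each fixed list were added. The lists were T-cell receptor signalling (such as CD3D, LCK, LAT and ZAP70), B-cell receptor signalling (CD79A, BTK), MHC class II presentation (CIITA, CD74, HLA-DRA), T-lineage regulators (TCF7, GATA3, BCL11B), B-lineage regulators (PAX5, EBF1, SPIB), co-stimulation and checkpoint (CD28, CTLA4, CD80), NF-kB targets (NFKBIA, RELB, EBI3), interferon response (ISG15, MX1, OAS3), S phase (MCM2, PCNA), G2 and M phase (CDK1, TOP2A), heat shock and early response (HSPA1A, FOS), mitochondrial transcripts, and genes of myeloid (LYZ, CST3), natural killer (NKG7, GNLY) and erythroid or platelet cells (HBB, PPBP). Lists were tested by camera with a preset correlation of 0.01 and with an estimated correlation. Alternatives were DESeq2, other scalings and filters, at least 200 genes per cell, classes from the other data type, a single probe side, a pseudocount of 5, a minimum of 50 counts, and leaving out each library. Doublet removal, the staining sets, the probe sides of macrophages and the removal of the cell with the highest count were added after the data were seen.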

Results

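The deposited data held single-cell counts of PLA products, each formed when an antibody probe of set A and an antibody probe of set B met on a cell, together with mRNA counts for part of the cells. A product therefore named a pair of proteins, and the sum over all products of a protein measured its level. The 18 samples comprised a mixture of Jurkat cells, a human T-cell leukaemia line, and Raji cells, a human B-cell lymphoma line, measured by Drop-seq (RNA and PLA), in sorted plates (PLA) and by 10x (RNA and PLA). Peripheral blood mononuclear cells (PBMC) were measured in plates (PLA) and by 10x (RNA and PLA). Primary human macrophages in plates (PLA) made up the other 10 samples: untreated, or given LPS, PAM2CSK4 (PAM) or both for 5 min, 2 h or 12 h. Each group was 1 sample, so no comparison had replicate samples within a group, and cells were not treated as replicates.

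The Drop-seq RNA table held 1514323 UMI over 700 barcodes. The 10x RNA table of Jurkat and Raji cells held 210281069 UMI over 8668 cells, and that of PBMC held 74662444 UMI over 12577 cells. PLA counts totalled 373635 in 800 Drop-seq barcodes, 365316 in 192 plate wells and 6346491 in the 8668 10x cells of the Jurkat and Raji mixture. For PBMC, they totalled 431660 in 382 plate wells and 11058905 in 12577 10x cells. The median PLA total per cell was 269 in Drop-seq, 1390.5 in the Jurkat and Raji plates, 374 in the 10x mixture, 1011.5 in the PBMC plates and 479 in PBMC 10x. Among macrophages, the kept cells of a sample numbered from 29 (untreated) to 36, and sample totals ran from 13796 (LPS 12 h) to 51075 (PAM 5 min). A single cell gave 51.0% of the PAM 5 min total. The sources do not state how PLA counts were collapsed to molecules, so the 95% intervals of PLA counts cover counting error only.

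The transcriptomes of the lines separated T-cell from B-cell genes. Jurkat-like cells had more mRNA of the T-cell signalling genes THEMIS, CD2, FYB1, CAMK4 and ZAP70. Raji-like cells had more mRNA of the immunoglobulin genes IGKC and IGHM, of HLA-DRA, HLA-DRB1 and CD74, which serve antigen presentation, and of the B-cell surface genes MS4A1 and CD40. Genes for the PLA targets PD1 and CD28 were higher in Jurkat-like cells, and those for PDL1, B7 and ICAM1 were higher in Raji-like cells. Cells were classed by PLA proteins, not by RNA, and their UMI were summed per platform and class: 223 Jurkat-like and 149 Raji-like Drop-seq cells, and 2567 and 2369 10x cells. Of 12706 tested genes, 3571 were higher in Jurkat-like and 2663 higher in Raji-like cells (edgeR quasi-likelihood with platform as a block and 1 residual degree of freedom, Benjamini-Hochberg adjusted p under 0.05). The balance rested on the method: DESeq2 called 1154 higher in Jurkat-like and 1417 higher in Raji-like cells, and edgeR without the low-count filter called 2826 and 3202. Of the 6234 genes that edgeR called with the filter, 5642 changed the same way in both platforms, and 1454 and 695 exceeded a log2 change of 2 in favour of Jurkat-like and Raji-like cells. Across genes, which are not independent replicates, the log2 changes of the platforms had a correlation of 0.646.

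Named by a rule fixed before the data were examined, the 12 leading Jurkat genes were THEMIS, CD2, USP44, XAF1, TSHR, FYB1, SMC1B, FXYD2, CAMK4, AGGF1, GYPC and ZAP70, with log2 changes from 3.35 (ZAP70) to 3.55 (THEMIS). THEMIS lies on chromosome 6 at 127696628 to 127918595 of GRCh38; its log2 change was 3.55 (SE 0.251, edgeR adjusted p 4.44e-43), and it was higher in both platforms. The leading Raji genes included IGKC, HLA-DRB1, IGHM, MS4A1, HLA-DRA, CD74, HLA-DQA1, SPARCL1, AC012236.1, VPREB3 and CD40, with log2 changes from -5.08 (IGKC) to -4.87 (CD40). IGKC lies on chromosome 2 at 88857361 to 88857683; its log2 change was -5.08 (SE 0.218, edgeR adjusted p 1.71e-113), and it was lower in Jurkat-like cells of both platforms. With 1 residual degree of freedom, p-values of this fit rest on a spread estimated over many genes. They do not measure how well the platforms agree on a gene. Among genes that code for the PLA targets, CD28 had a log2 change of 3.47, CD3E of 3.11, PDCD1 (PD1) of 3.93 and ITGAL (LFA1) of 1.38. The corresponding values were -4.72 for CD80 (B7), -3.91 for ICAM1 and -4.31 for CD274 (PDL1). The PDCD1 value rested on the 10x library, since Drop-seq held 3 counts in Jurkat-like and 0 in Raji-like cells. BSG (CD147) at -0.03 (edgeR adjusted p 0.903) and PTPRC (CD45) at 0.34 (adjusted p 0.104) missed the threshold, and the CD4 gene was not tested. In the 10x library, the 12 Jurkat genes reached 5.21% of their Jurkat-like level in Raji-like cells, a class in which 8.06% of cells were called doublets. Without doublets the 99th percentile of the log2 changes was 5.67 against 3.49 with them, so the sizes of the Jurkat-high changes are limited by the make-up of the classes.

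Genes of T-cell receptor signalling, B-cell receptor signalling, MHC class II presentation and NF-kB targets moved nearly as whole lists. Of 24 tested T-cell receptor genes, 20 were higher in Jurkat-like and 0 in Raji-like cells, with a median log2 change of 3.06, and LCP2 at 3.51 followed THEMIS. B-cell receptor genes gave 17 of 18 higher in Raji-like cells (median -4.44), and all 15 MHC class II genes were higher in Raji-like cells (median -4.48). NF-kB targets gave 14 of 15 higher in Raji-like cells (median -3.59), led by EBI3 at -5.19, BCL2A1 at -4.55 and LTA at -4.43. T-lineage regulators gave 12 higher in Jurkat-like and 3 higher in Raji-like cells (median 2.93), with BCL11B at 3.38 and LMO2 at -4.52. LMO2 rested on the 10x library, since its Drop-seq CPM were 1.38 in Jurkat-like and 1.87 in Raji-like cells. B-lineage regulators gave 2 and 10 (median -3.42), with PAX5 at -4.82, MEF2C at -4.75 and SPIB at -4.60. Co-stimulation genes gave 7 and 10 (median -2.45), including CD27 at -4.73. For 3 myeloid genes, AIF1 (3.10), CST3 (3.05) and CTSB (2.27), all were higher in Jurkat-like cells. The camera test with a preset correlation of 0.01 gave an adjusted p of 7.52e-10 for T-cell receptor and NF-kB genes, 2.47e-13 for B-cell receptor genes, 6.32e-14 for MHC class II, 0.000387 for T-lineage, 1.47e-05 for B-lineage, 0.0181 for co-stimulation and 0.00454 for myeloid genes. With an estimated correlation, 0 of these calls held, each with a camera adjusted p of 0.497. That correlation came from 1 residual degree of freedom, so this loss cannot decide whether the lists moved.

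The remaining lists showed no call by camera. Interferon genes gave 11 higher in Jurkat-like and 4 higher in Raji-like cells (median 1.11, camera adjusted p 0.218), with OAS3 at 3.17, IFI44 at 2.91 and IFITM1 at 2.86. IFITM1 rested on the 10x library, since its Drop-seq value was -0.42. S-phase genes gave 4 and 2 (median 0.17, adjusted p 0.569), led by UHRF1 at 1.41, TYMS at 1.38 and CDC45 at 0.88. G2 and M phase genes gave 1 and 3 (mean -0.12 beside a median of 0.00, adjusted p 0.281), with UBE2C at -1.38, BIRC5 at -0.47 and PLK1 at -0.46. Heat shock genes gave 3 and 4 with a median of -0.03 although camera pointed to Jurkat-like cells (adjusted p 0.865), with DNAJB1 at 1.32, JUNB at -1.24 and HSPA1B at -1.01. HSPA1B changed sign between the platforms, with 0.45 in Drop-seq and -1.32 in 10x. Mitochondrial transcripts gave 1 and 3 (median -0.20, adjusted p 0.218), with MT-ND5 at -0.93, MT-ND4L at 0.75 and MT-CO3 at -0.53. A single natural killer gene was tested, NKG7 at 1.29, and 0 erythroid or platelet genes passed the count filter. Adjusted over the list alone, the counts were the same for every list except G2 and M phase, with 0 higher in Jurkat-like and 2 higher in Raji-like cells.

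At the protein level, CD3, CD28 and PD1 marked Jurkat-like cells. HLADR, ICAM1 and PDL1 took larger shares of PLA counts in Raji-like cells on every platform. CD147, a widely expressed surface glycoprotein, took a larger share in Jurkat-like cells on every platform. Its mean count per cell in Drop-seq was instead lower in Jurkat-like cells, at 126 against 233. Classes came from RNA clusters in Drop-seq and 10x and from the well names in plates. Of 11 proteins shared by the panels, 3 passed the test (edgeR quasi-likelihood on counts scaled to the PLA total, platform as a block, 2 residual degrees of freedom, Benjamini-Hochberg). CD3 had a log2 change of 4.77 (SE 1.12, edgeR adjusted p 0.00196), CD28 of 4.70 (SE 1.16, adjusted p 0.00196) and PD1 of 4.62 (SE 1.11, adjusted p 0.00196), each higher in 3 of 3 platforms. HLADR at -2.74 and ICAM1 at -2.55 (edgeR adjusted p 0.0591 for both) and PDL1 at -2.10 (adjusted p 0.0999) missed the threshold. CD147 at 1.47 and CD4 at 1.15 (both 0.192), B7 at -1.20 (0.199), LFA1 at 0.58 (0.504) and CD45RA at 0.06 (0.95) missed it too. The count of proteins past the threshold rested on the platforms: it was 0 without 10x and 7 without the plates. It rested on scaling too: TMM and DESeq2 each called 3 proteins higher in Jurkat-like and 4 higher in Raji-like cells. In 10x, Jurkat-like cells held 12.6% of the Raji-like mean count of HLADR, 12.5% of ICAM1 and 12.8% of PDL1. These means pool 10x cells with unlike control probes: for ICAM1 the percent was 6.1 in cells with the control probes named Full and 81.9 in those with the other control probes. Most cells could not be given either set: 3044 of 3372 Jurkat-like and 1235 of 2208 Raji-like 10x cells. Among these unassigned cells the ICAM1 percent was 15.1. In plates, the same values were 1.51%, 2.84% and 6.44%.

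**Figure D1:**
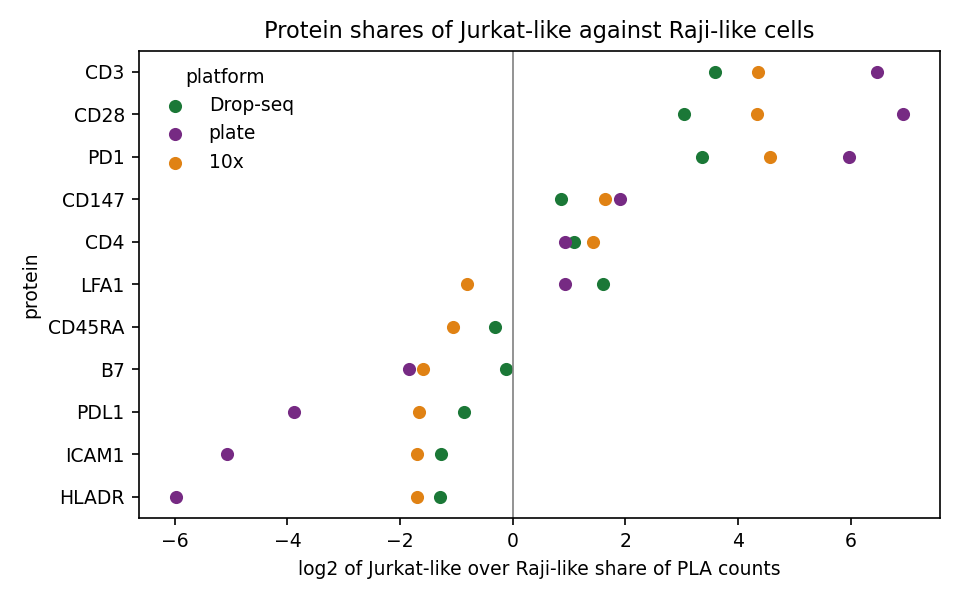
Each point gives, for a protein and a platform, the log2 ratio of its share of PLA counts in Jurkat-like cells to that in Raji-like cells (x axis), with no error bar since each platform was 1 library. CD3, CD28 and PD1 lie between 3.03 and 6.93, HLADR between -5.98 and -1.29, and CD45RA has no plate point because Raji-like wells held 0 counts.

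Protein proximity was read as the observed count of a product over the count expected if probes met in proportion to their totals in each cell. Homotypic products, in which both probes target the same protein, exceeded expectation for CD28, CD3, PD1 and CD147 in Jurkat-like cells. CD28 is a disulfide-linked homodimer, and CD3 chains sit in a multi-chain receptor. In Raji-like cells, the homotypic products of HLADR, ICAM1 and PDL1 exceeded expectation, while HLADR with ICAM1 fell below it. For CD28:CD28 in Jurkat-like cells, the ratio was 6.34 in Drop-seq (95% exact Poisson interval 4.53 to 8.64), 2.34 in plates (2.27 to 2.41) and 5.09 in 10x (5.03 to 5.16). Its size rested on the expectation used: the 10x value was 10.2 under the iterative expectation. CD3:CD3 gave 1.82, 1.39 and 4.16 in the same order, PD1:PD1 gave 1.57, 1.03 and 1.35, and CD147:CD147 gave 1.56, 1.08 and 1.40. The heterotypic pairs CD28:CD3 (1.42, 0.820 and 1.56) and CD28:PD1 (1.26, 0.835 and 1.08) were above 1 in the droplet platforms and below 1 in plates, but CD28:CD3 in plates turned to 1.24 under an iterative expectation, which removes excess products from the probe totals. In Raji-like cells, HLADR:HLADR gave 1.24, 1.29 and 1.33, ICAM1:ICAM1 gave 1.30, 1.04 and 1.23, and PDL1:PDL1 gave 1.19, 2.79 and 1.21. HLADR:ICAM1 gave 0.872, 0.920 and 0.879, and B7:PDL1 gave 0.958, 0.529 and 1.06. The 10x value of B7:PDL1 fell below 1 in some alternatives. It was 0.784 with pooled totals, 0.989 in cells of middle totals and 0.582 in the control set other than Full. In Jurkat-like cells CD3:CD4 gave 0.799 (0.383 to 1.47) in Drop-seq, 1.19 (1.04 to 1.36) in plates and 1.97 (1.59 to 2.42) in 10x, where the Drop-seq interval covered 1. Ratios were largest where a protein was scarce: CD3:CD3 in Raji-like 10x cells gave 89.9 from 221 observed and 2.46 expected counts, and HLADR:HLADR in Jurkat-like 10x cells gave 4.03. HLADR:ICAM1 likewise stood above 1 in Jurkat-like cells, at 1.51, 2.42 and 1.72. Under the iterative expectation, HLADR:ICAM1 on Raji-like cells rose to 1.04 in Drop-seq and 1.0 in 10x.

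**Figure D2:**
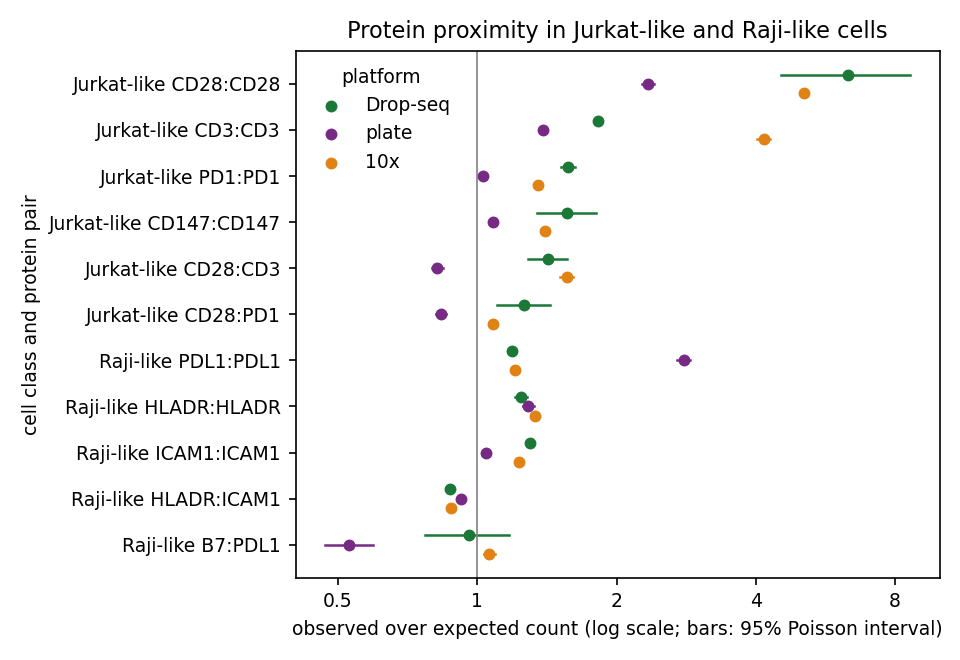
Observed over expected counts (x axis, log scale) of fixed and homotypic protein pairs in Jurkat-like and Raji-like cells, where each point is a platform and each bar its 95% exact Poisson interval. CD28:CD28 in Jurkat-like cells lies at 6.34, 2.34 and 5.09, and HLADR:ICAM1 in Raji-like cells lies between 0.872 and 0.920.

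Class names from CD3, CD28, PD1, HLADR, ICAM1 and the other PLA markers were compared with names from RNA markers such as CD3D, CD3E, CD79A and MS4A1 in the same barcodes. In Drop-seq, 361 of 372 cells had the same name by both, which is 97.0% (95% exact Clopper-Pearson interval 94.8 to 98.5). In 10x, 4368 of 4419 cells with both names matched, which is 98.8% (98.5 to 99.1). A further 1161 of the 5580 RNA-named 10x cells, 20.8%, had no PLA name, and these were 32.7% of Jurkat-like and 2.58% of Raji-like cells. In plates, all 87 wells named for T cells and all 70 named for B cells that passed the count minimum carried the matching PLA name.

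Surface proteins of PBMC followed the classes set from RNA. Ranks below are among the named classes only, and clusters left unnamed, such as cluster 13 with 368 cells, were not ranked. CD14 and CD9 were highest on classical monocyte-like cells, and CD8 on CD8 T-like cells. CD38 was highest on NK-like cells, and CD16 was highest on FCGR3A monocyte-like cells ahead of NK-like cells. HLADR was high on B-like, monocyte-like and plasmacytoid dendritic-like cells, the classes that present antigen. The classes held 4096 CD4 T-like, 1187 CD8 T-like, 1244 NK-like, 264 B-like, 726 classical monocyte-like, 322 FCGR3A monocyte-like and 35 plasmacytoid dendritic-like cells, and each comparison below is a mean PLA count per cell within 1 library. CD8 averaged 721 on CD8 T-like and 50.1 on CD4 T-like cells, and CD4 averaged 282 on CD4 T-like and 52.4 on CD8 T-like cells. CD4 was also counted on plasmacytoid dendritic-like (230), classical monocyte-like (178) and FCGR3A monocyte-like cells (161). CD3 averaged 129 on CD4 T-like and 141 on CD8 T-like cells against 25.5 on NK-like cells. HLADR averaged 1747 on B-like cells and 60.6 on NK-like cells. CD14 averaged 63.5 on classical and 14.8 on FCGR3A monocyte-like cells, CD9 averaged 3333 and 813, and CD16 averaged 40.9 on FCGR3A monocyte-like and 22.4 on NK-like cells. CD38 averaged 218 on NK-like and 172 on plasmacytoid dendritic-like cells, while CD56 averaged 19.8 and 24.7. As a share of PLA counts, CD56 was higher on NK-like cells than on any other class, with a ratio of 2.90. As a background level, CD8 averaged 178 and CD3 averaged 77.4 on classical monocyte-like cells, a class with the highest PLA totals and 0.114 CD8A and CD8B counts per 10000 UMI, so a CD4 count of the same size there does not by itself show the protein. CD4 mRNA, however, stood at 2.39 counts per 10000 UMI in that class. It stood at 2.62 in FCGR3A monocyte-like and 3.02 in plasmacytoid dendritic-like cells, against 0.660 to 1.07 in the CD4 T-like clusters. By cell, CD4 exceeded CD8 in 3810 of 4096 CD4 T-like cells (93.0%), and CD8 exceeded CD4 in 1103 of 1187 CD8 T-like cells (92.9%). CD16, too, as a share of PLA counts, was higher on NK-like than on FCGR3A monocyte-like cells, with a ratio of 0.526.

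**Figure D3:**
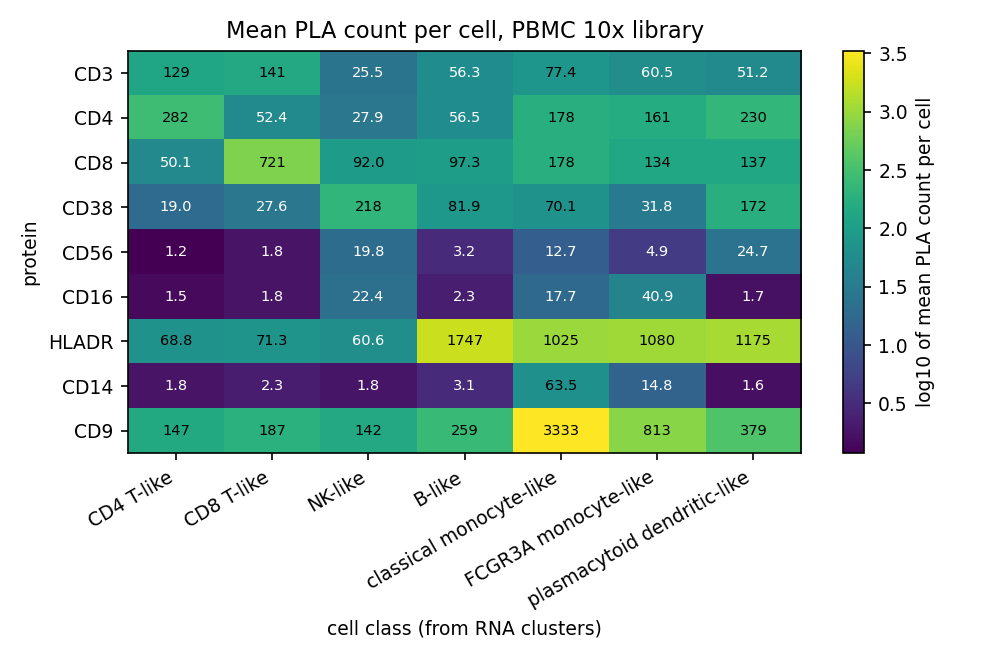
Mean PLA count per cell (number in each tile, colour on a log10 scale) of 9 surface proteins (y axis) in the 7 PBMC classes named from RNA (x axis) of the 10x library. CD8 stands at 721 in CD8 T-like cells against 178 or less elsewhere, and CD9 stands at 3333 in classical monocyte-like cells.

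In PBMC, CD3 exceeded expectation with CD4 on CD4 T-like cells and with CD8 on CD8 T-like cells, the coreceptor pairs of the T-cell receptor, but these pairs were higher still on classes that are not T cells. CD28 again stood out for its homotypic product. CD8 and CD9, a tetraspanin abundant on platelets and monocytes, met less often than expected in the 10x classes and in part of the plate clusters. On CD4 T-like 10x cells, CD3:CD4 was at 1.24 times expectation (1.24 to 1.25), CD3:CD8 at 0.981, CD28:CD28 at 6.05 and CD28:CD3 at 1.05. On CD8 T-like 10x cells, CD3:CD8 was at 1.09, CD3:CD4 at 1.40, CD8:CD8 at 1.26 and CD28:CD28 at 9.91, where CD4 and CD28 were scarce. CD3:CD4 was at 2.40 on NK-like, 4.19 on B-like and 3.14 on classical monocyte-like cells, and CD3:CD8 was at 1.17, 2.45 and 2.88. CD28:CD28 likewise was at 25.8 on classical monocyte-like cells, so the ratios do not single out T cells. Over all 345 kept plate wells, CD3:CD4 was at 1.25, CD3:CD8 at 1.10, CD28:CD28 at 3.10 and CD28:CD3 at 0.657. CD8:CD9 was at 0.247 on CD8 T-like 10x cells, at 0.303 on CD4 T-like 10x cells and at 0.510 over the plate wells. It differed between CD8 T-like clusters, with 0.530 in cluster 12 (371 cells), 0.199 in cluster 17 (244 cells) and 0.102 in cluster 7. In plates, PLA cluster 2 (66 wells, mean CD8 count 1656) had 0.770 and cluster 1 (84 wells, mean CD8 count 2598) had 0.145. Of the CD4-rich plate clusters, cluster 3 had 0.440, while cluster 0 at 1.05 (0.880 to 1.24) and cluster 4 at 1.18 (0.857 to 1.58) showed no depletion. Under the iterative expectation, CD8:CD9 rose above 1 in 10x clusters 7, 12 and 17 and plate clusters 1 and 2, so its depletion held only relative to total probe counts.

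Macrophages carried the endotoxin and lipopeptide receptors TLR2, TLR4 and CD14 together with CD36, a scavenger receptor. The comparison over time asked whether LPS, a TLR4 ligand, or PAM2CSK4, a TLR2 ligand, changed the share of a protein, and that between stimuli asked whether the ligands differed. The share of IL-8Rb, a chemokine receptor also named CXCR2, was higher at 12 h than at 5 min in 3 of 3 stimuli, without passing the test. CD36 took 41.0% of the counts in untreated macrophages, TLR4 6.49%, TLR2 4.67%, CD14 0.915% and TLR6 0.737%. IL-8Rb took 7.59% of counts in untreated macrophages (95% exact Poisson interval 7.34 to 7.85). At 5 min it took 8.06% with LPS, 6.64% with PAM and 6.94% with both, and at 12 h it took 9.59%, 11.6% and 9.71%. Its mean count per cell instead went down in 3 of 3 stimuli, from 131 to 82.7 with LPS, from 206 to 123 with PAM and from 122 to 81.2 with both. The PAM value rested on the cell that held 51.0% of the 5 min counts: without it the 5 min mean was 120 and the share 7.69%, so the mean no longer went down. For LPS, PAM and both, TLR2 took 4.66%, 4.53% and 5.09% at 5 min, 6.55%, 4.95% and 5.28% at 2 h, and 4.97%, 6.21% and 4.62% at 12 h. CD14 ranged from 0.359% at 12 h of both stimuli to 2.00% at 2 h of PAM. With edgeR quasi-likelihood on the 9 stimulated samples and stimulus as a block, 0 of 15 proteins passed at 12 h against 5 min (1 at an unadjusted p under 0.05, 2 past the threshold by DESeq2, both higher at 12 h, and 3 by limma on per-cell shares, all lower) and 0 at 2 h (0 unadjusted, 0 by DESeq2, 0 by limma). IL-8Rb came nearest with a log2 change of 0.52 at 12 h (SE 0.134, edgeR adjusted p 0.0873), and within plates it was higher in 11 of 12 comparisons of a stimulus with its 5 min sample (median log2 change 0.48). These comparisons divided the cells of the same samples by plate, so they add no replicate of the treatment. Between stimuli, 0 of 15 proteins passed for PAM against LPS, both against LPS or both against PAM (edgeR, 0 at an unadjusted p under 0.05 in each, 0 by DESeq2 in each). Of 146 PLA products, 0 passed at 12 h (edgeR, 2 at an unadjusted p under 0.05, 1 past the threshold by DESeq2) and 0 at 2 h (1 unadjusted, 0 by DESeq2).

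Receptor pairs of macrophages were near expectation for most TLR heterodimers and above it for several homotypic products, and below it for those of MMP16 and IL-10R. IL-1R with IL-1R stood highest over all cells, and TLR2 with TLR2 followed. CD14, which hands LPS to TLR4, exceeded expectation with TLR4, while MD2, the TLR4 coreceptor, did not. Both rest on a single probe side: untreated cells gave 6 CD14 counts from probe A and 404 from probe B, and 2269 and 45 for MD2. Over all 326 kept cells, IL-1R:IL-1R was at 6.01 (95% exact Poisson interval 5.48 to 6.58), TLR2:TLR2 at 2.47, CD14:TLR6 at 1.92, TLR1:TLR6 at 1.89, CD14:TLR4 at 1.47 and TLR4:TLR4 at 1.33. TLR1:TLR2 was at 1.11, TLR2:TLR6 at 1.05, CD14:TLR2 at 1.04, TLR2:TLR4 at 1.03, CD36:TLR2 and CD36:TLR4 each at 0.940, MD2:TLR4 at 0.863 and CD14:CD36 at 0.792. Homotypic products below expectation were MMP16:MMP16 at 0.487 (0.417 to 0.567) and IL-10R:IL-10R at 0.772 (0.657 to 0.90). CD36:CD36 at 1.06, TGFBR1:TGFBR1 at 0.991 and MD2:MD2 at 0.906 had intervals that covered 1. For 30 products, each with a fixed order of its probes, limma on the log2 ratio of observed to expected counts gave 2 higher at 12 h than at 5 min and 1 higher at 2 h. IL-1R:IL-1R rose by 0.72 at 12 h (SE 0.111, limma adjusted p 0.0259) and by 0.68 at 2 h (limma adjusted p 0.0325), in 3 of 3 stimuli at each time. IL-8Rb:TLR4, with IL-8Rb as probe A and TLR4 as probe B, rose by 0.62 at 12 h (SE 0.126, limma adjusted p 0.0499), in 3 of 3 stimuli. The reverse order of this pair was not among the calls. IL-1R:IL-1R was at 6.25 in untreated cells, at 4.25, 4.04 and 4.58 at 5 min of LPS, PAM and both, and at 6.70, 7.48 and 8.45 at 12 h. At 2 h it was at 8.48, 5.49 and 6.96 in the same order, so the PAM value lay below the untreated one. From 5 min to 12 h its observed count went from 33 to 66 with LPS, 34 to 29 with PAM and 35 to 35 with both. The expected count went from 7.76 to 9.84, 8.42 to 3.87 and 7.65 to 4.14, so with PAM and both the ratio rose through the expected count. Sample PLA totals were lower at 12 h than at 5 min in every stimulus, so time cannot be told apart from PLA depth. IL-8Rb:TLR4 was at 0.389 in untreated cells, at 0.379, 0.373 and 0.257 at 5 min and at 0.448, 0.629 and 0.457 at 12 h. Within plates, IL-1R:IL-1R was higher at 2 h in 12 of 12 comparisons and at 12 h in 7 of 12, and IL-8Rb:TLR4 was higher at 12 h in 8 of 12. The plates hold cells of the same samples, so these comparisons are not independent of the calls. All 3 calls were lost with totals pooled over cells, and both IL-1R:IL-1R calls with the iterative expectation, under which IL-8Rb:TLR4 had too few counts to be tested.

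**Figure D4:**
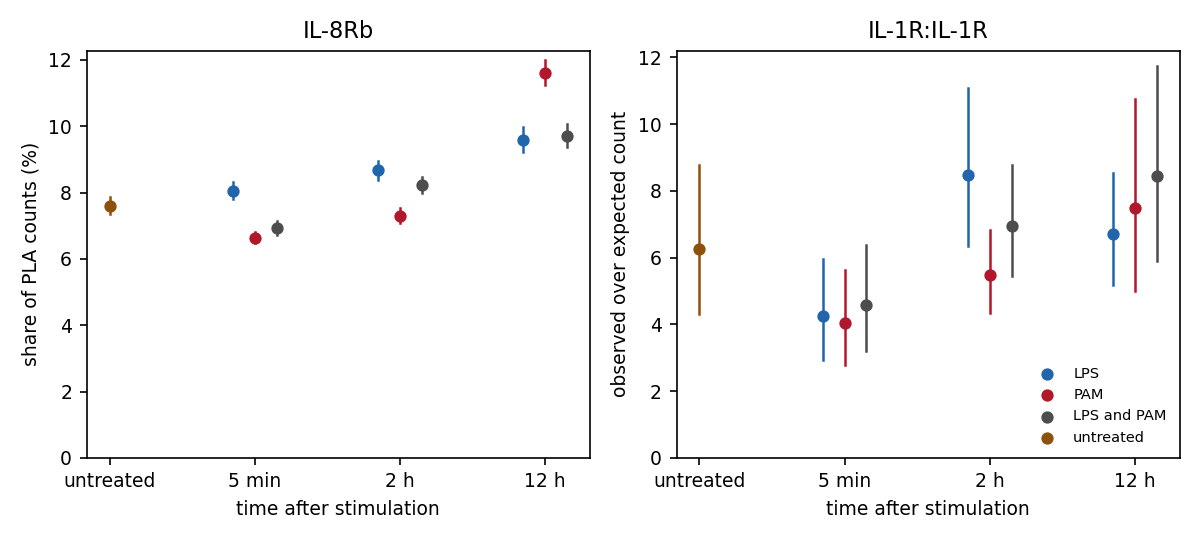
The left panel gives the share of IL-8Rb in PLA counts (y axis, percent) and the right panel the observed over expected count of IL-1R:IL-1R (y axis), by time after stimulation (x axis); points are samples and bars are 95% exact intervals for counting error. IL-8Rb stands at 7.59% in untreated cells and at 9.59 to 11.6% at 12 h, while IL-1R:IL-1R at 12 h (6.70 to 8.45) lies at or above the untreated value of 6.25.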

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

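The tests of free PLA products (the comparison within the Full staining set included), of expression by Jurkat cells, of HLADR, PDL1 and B7 in plates, of doublets in the Raji-like class and of expression by Raji cells were chosen after the result was seen. Under PAM and LPS, the shares of 9 of 15 macrophage proteins moved in opposite directions from 5 min to 2 h with both 95% counting intervals clear of 0, and 0 of 15 did so at 12 h. The PAM change minus the LPS change on the log2 scale was 2.94 for CD14, -0.43 for CD36, 0.33 for IL-10R, 0.35 for IL-6Ra, 0.55 for LBP, 0.86 for MMP15, 1.26 for TLR1, 1 for TLR4 and 1.56 for TLR6. Without the cell with the highest count these values were 1.93, -0.26, 0.38, 0.22, 0.20, 0.61, 0.86, 0.74 and 1.15 in the same order. Each time and stimulus was a single sample, and 51.0% of the PAM 5 min counts came from 1 cell. Without that cell, the same criterion held for 7 of the 9 proteins at 2 h, not for IL-6Ra and LBP, and newly for IL-8Rb and TLR2. At 12 h it then held for 2 proteins, IL-1R and LBP, so the count of 0 at 12 h rested on that cell. What set these differences was not tested. In Drop-seq, 211 of 800 PLA barcodes had no RNA barcode, with a median of 158 PLA counts against 317 for those with RNA. They were left out of the joined comparisons, and why they lack RNA was not tested.

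Over all 10x cells, HLADR, ICAM1, PDL1 and B7 were counted on Jurkat-like cells at a similar percent of their Raji-like means, with a highest over lowest ratio of 1.08, as free PLA products shared by all droplets would give. Within the Full set alone the percent ran from 6.1 for ICAM1 to 9.42 for HLADR, a ratio of 1.55, CD45RA stood at 19.6 over all 10x cells, and in Drop-seq the percent ran from 12.2 for HLADR to 27.7 for B7, so free products may account for part of these counts, as a hypothesis tested on the same data. Doublets would leave the typical cell low, yet the median singlet held at least 0.864 of the mean for HLADR, ICAM1 and PDL1. From the Full set to the other set, ICAM1 went to 0.0689 of its level on Raji-like cells but only to 0.925 on Jurkat-like cells, and HLADR in plates, where no droplets are shared, was at 0.120 of its 10x percent, which argues against expression by Jurkat cells as the main source of these 2 proteins. For ICAM1 this covers only the 139 Full and 189 other Jurkat-like cells that could be given a set, of 3372. For PDL1 and B7 expression by Jurkat cells cannot be told apart from free products, since the plate percent was at 0.502 of the 10x percent for PDL1 and at 1.97 for B7, although B7 on Jurkat-like cells kept 0.880 between the staining sets.

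The Jurkat-high RNA changes had a 99th percentile of 3.49 on the log2 scale, which rose to 5.67 without called doublets, a rise of 2.18. With classes from RNA clusters, which leave out the unnamed 10x cluster of highest median UMI count (57327) but no cell for a doublet call, it was 6.04, so the way cells were classed may act beside or in place of doublets. Doublets in the Raji-like class would give the rise, and even expression by all Raji cells would not. Cells are called doublets for a mixed transcriptome, so the rise cannot separate doublets from expression by a part of the Raji cells. The tested genes changed too: 5732 of the 6234 edgeR calls were tested without called doublets. Free RNA would reach the typical cell, yet the median Raji-like cell held 0 of the mean share of the 12 Jurkat genes, although the median Jurkat-like cell held 0.171 of the mean share of the 12 Raji genes. Both doublet tests rest on called doublets of the 10x library alone.

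CD8:CD9 stood at 0.530 in 10x cluster 12 and 0.102 in cluster 7, and at 0.770 and 0.145 in plate clusters 2 and 1, a difference that was gone under the iterative expectation (1.14 and 1.12, and 1.05 and 1.12). Among cells of 1 range of PLA totals, the lower of the 10x and plate ratios was 5.80, that of 10x (184 and 253 cells), which argues against PLA depth there. The plate ratio of 8.27 rested on only 9 and 6 wells. Without cells that held a platelet gene count the 10x ratio was 5.14, but only 2 cells in each cluster held such a count, so platelet fragments without RNA were not tested. Free CD9 products cannot be told apart from a difference in proximity, since the CD8:CD9 ratio between clusters was 3.30 times the median of the other CD9 pairs for 10x clusters 12 and 7, but 1.76 times for 12 and 17, where CD9:PD1 at 5.10 differed more than CD8:CD9 at 2.67, and 1.51 times in plates, where CD3:CD9 at 6.80 differed more than CD8:CD9 at 5.30. No biological explanation was tested.

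Other splits of the samples numbered 10 for each fit, the real one included, too few for a share under 0.05. They were drawn over all sums of a comparison and ignored the block of the fit. Some therefore put both sums of a block on the same side. For macrophage proteins, the real count was 0 and the highest other count 6 at 12 h, 8 at 2 h, 7 for PAM against LPS, 7 for both against LPS and 2 for both against PAM. With a real count of 0, 10 of 10 splits give as many whatever the data, so this share decides nothing. For PLA products, the real count was 0 too, so the share of 10 of 10 splits again decides nothing, and the highest other count was 63 at 12 h and 60 at 2 h. Such high counts, drawn from splits that were not held within stimulus, point to a structure of the samples, whose nature was not tested. For macrophage proximity, the real count was 2 with a highest other of 4 at 12 h, in 2 of 10 splits as many, and 1 with a highest other of 0 at 2 h, in 1 of 10 splits. For proteins of the lines, the real count was 3 with a highest other of 0, in 1 of 10 splits.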

How the results depend on the processing

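The tests without called doublets, by staining set, by probe side in macrophages and without the cell with the highest count were chosen after seeing the data, and the cause of the changes below was not tested. For RNA of the lines, DESeq2 called 2571 genes (1154 higher in Jurkat-like cells, 1417 in Raji-like cells) against 6234 by edgeR, and all 2571 were among the edgeR calls. Without the low-count filter the log2 change shifted by a median of -0.226 over the genes tested both ways. HSPA1B was at -1.32 without Drop-seq and 0.45 without 10x, and IFITM1 was at 2.82 without Drop-seq and -0.42 without 10x. In simulated RNA with a dispersion of 0.05, edgeR recovered 13% of 100 genes changed by 1 on the log2 scale and 85.7% of 98 changed by 2. These were among 13030 tested genes. Far more genes were called in the real data, so the recovered shares do not give the power of the real fit. For proteins of the lines, 3 passed; TMM and DESeq2 each gave 7, probe A alone 5, PLA classes 5 and the Full set 5. The count was 7 without the plates and 0 without 10x. For macrophage proteins at 12 h, 0 passed; DESeq2 gave 2, per-cell shares 3, a fit without stimulus 1 and probe A alone 1. It was 1 without LPS 2 h, LPS 12 h or PAM 2 h and 0 without any other sample. For products at 12 h, DESeq2 gave 1 against 0. Proximity at 12 h had 2 calls; pooled totals, the iterative expectation and a minimum of 50 gave 0 (the minimum left neither called product tested, and the iterative expectation left IL-8Rb:TLR4 untested), and removal of the highest cell gave 1. Without LPS 12 h there were 5, without LPS 2 h or PAM 2 h 1, and without any other sample 0. Proximity at 2 h had 1 call; pooled totals and the iterative expectation gave 0, and a minimum of 50, which left the called product untested, gave 0. Without PAM 12 h there were 2, without LPS 2 h, LPS 12 h or PAM 2 h 1, and without any other sample 0. HLADR:ICAM1 on Raji-like cells rose to 1.04 in Drop-seq and 1.0 in 10x under the iterative expectation, and CD28:CD3 on Jurkat-like plate cells rose to 1.24. CD28:CD28 in 10x was 10.2 by the iterative expectation, 6.08 with pooled totals, 5.35 in cells of middle totals, 4.94 in the Full set and 5.21 in the other control set. HLADR:HLADR in 10x was 1.40, 1.74, 1.30, 1.34 and 1.28 in the same order. B7:PDL1 in 10x was 0.784 with pooled totals, 0.989 in cells of middle totals and 0.582 in the control set other than Full. CD8:CD9 under the iterative expectation was 1.14 in cluster 12, 1.12 in cluster 7, 1.19 in cluster 17, 1.11 in all CD8 T-like cells, 1.12 in plate cluster 1 and 1.05 in plate cluster 2. With pooled totals it was 0.427 in cluster 12 and 0.0808 in cluster 7, and in cells of middle totals it was 0.0900 in cluster 7. As a share of PLA counts, CD16 on FCGR3A monocyte-like cells was at 0.526 of the highest other class and CD56 on NK-like cells at 2.90, both reversed from mean counts. Per cell, IL-8Rb against untreated was at -0.044 for LPS 2 h, -0.50 for LPS 12 h, 0.81 for PAM 5 min, 0.061 for both at 5 min and -0.53 for both at 12 h, each of opposite sign to its share. The PAM 5 min values rested on the cell with the highest count: without it IL-8Rb was at 0.019 by share and 0.038 per cell, so both had the same sign. TLR2 at PAM 12 h was at -0.13 per cell.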

Other observations

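In untreated macrophages, CD36 was counted 14 times from probe A and 18356 times from probe B, so pairs with CD36 rest on 1 side of the panel. LBP (1675 and 8), CD14 (6 and 404) and MD2 (2269 and 45) were uneven too, to a lesser degree. In the 10x mixture, ICAM1 on Raji-like cells of the staining set other than Full was at 0.0689 of the Full set and B7 at 0.0655. These counts thus differed within 1 library between cells with unlike control probes, and whether the staining itself differed was not tested. The labels do not say what the Full set and the other set of control probes stand for.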
